A study of Mus musculus with 2 samples.

How the data were processed

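RNA sequencing was carried out on lymphatic endothelial cells (LECs) from the skin of mouse embryos at E15.5 (embryonic day), strain C57BL/6. There were 2 libraries. The first was labelled wild type (the control library) and the second was labelled Dot1l knockout. Dot1l encodes the histone methyltransferase that places methyl groups on lysine 79 of histone H3. Per the labels' protocols, each library was made from total RNA that had been pooled from 2 to 3 biological replicates, and RNA with an integrity number above 7.0 was converted to libraries with the ScriptSeq v2 kit. The knockout is described there as endothelial. The labels also carry a growth protocol for cultured primary dermal LECs, and the series title names a DOT1L inhibitor. Whether the sequenced cells were cultured, and how they were purified, is not given in the sources used here.

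Each library came as a list of gene symbols with 1 value per gene. The values were taken as FPKM (fragments per kilobase of transcript per 1000000 mapped fragments) as deposited by the authors, because the submitters' processing notes name Cufflinks 2.2.1 and Cuffnorm and the values are decimal, never negative and do not sum to 1000000. STAR 2.5.2b, R 3.3.2 and the genome build mm9 are also named in the submitters' processing notes. The roles of these tools, the gene annotation and any scaling between the libraries are not given in the sources used here. Both lists held the same 24319 rows in the same order. A symbol or synonym in the reference tables matched 24209 of them. A spreadsheet had turned the symbols of 27 rows into dates (25 distinct strings, covering septin and membrane-associated ring finger genes), and these rows were kept in totals but not named. No mitochondrial gene was listed under the usual symbols, so that list gave no value. The lists carry no coordinates and the reference annotation is for another build than mm9, so no coordinates are given.

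The deposited FPKM summed to 415537 in the control library and 530294 in the library labelled Dot1l knockout. The depth is not stated. It was estimated from the low values, because 1 fragment adds a fixed amount to FPKM multiplied by transcript length. For genes with a single annotated transcript of at least 2500 nt, an assumed fragment length of 200 nt and up to 5 fragments, 82.4% of 159 control values and 76.0% of 175 values of the other library lay within 0.1 of a whole number of fragments. The step was the best of 500 scanned. The same scan on 100 sets of values scrambled by random factors gave at most 34.2% and 33.6%. The steps imply about 10300000 and 9090000 fragments, if no further scaling was applied. At that depth 1 FPKM in a transcript of 2 kb rests on about 20.5 and 18.2 fragments. Whole fragments were not recovered for all genes, so no count model was run. Values listed at exactly 0 (8138 and 7943 rows) can be failed estimates: Hmgcs1, a gene of cholesterol synthesis that most cells use, is at 0 in both libraries.

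With 1 library per genotype no test, p-value or standard deviation between replicates can be had, and none is given. Differences are on the scale log2(FPKM + 1), library labelled knockout over control, which understates the change of genes with low values. Folds printed for single genes are ratios of the deposited FPKM. Genes with at least 1 FPKM in at least 1 library were kept, and a gene was counted as higher or lower when the log2 difference reached 2-fold. For 32 gene lists the median difference was set against 10000 random lists of the same size drawn with replacement from genes matched in 10 bins of mean expression. A list was called apart when its percentile was under 2.5 or over 97.5, which describes these 2 libraries and is not a test of the genotype. Genes are not replicates. Some genes are members of several lists, so the lists are not independent of each other. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. Another 5 lists (mast cell and basophil, neutrophil, lymphocyte, adipocyte, imprinted genes) and the comparison with the pan-endothelial list were chosen after seeing the data. Named genes are Dot1l, members of the lists, and the 15 highest and 15 lowest by log2 difference among genes with at least 10 FPKM in at least 1 library, leaving out small RNAs, predicted genes and clone names. Small RNAs here are symbols of microRNAs and of small nucleolar, small nuclear and ribosomal RNAs. Other RNA genes, such as Rprl3 and Rprl2, were not left out. The few other genes that are named were chosen after their values were seen. Some members of the lists are not reported here by name.

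The alternatives were pseudocounts of 0.1 and 5, rescaling of each library to a sum of 1000000, to the same upper quartile or to the median gene, no minimum or a minimum of 5 FPKM, thresholds of 1.5-fold and 3-fold, leaving out small RNAs or markers of other cell types, unmatched random lists, and list means. No library could be left out. The code was tested on simulated libraries made from the 12147 genes at 1 FPKM or more in the control library: all 50 genes changed by 4-fold and 84.0% of 50 changed by 2.5-fold passed the 2-fold threshold, against 0.03% of unchanged genes, and 2.7% of 300 unchanged lists of 25 genes were called apart. The changed genes had at least 10 FPKM in control. The noise was independent between genes and its size was chosen, not measured. These shares check the code and are not error rates for the 2 real libraries. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.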

Results

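The transcriptomes of embryonic skin LECs labelled wild type and Dot1l knockout were compared, which asks how loss of this histone H3 lysine 79 methyltransferase in endothelium bears on gene expression in lymphatic vessels at E15.5 (embryonic day). Each genotype was represented by 1 library of pooled RNA, so none of the differences has a replicate check. If no further scaling was applied to the deposited values, the 2 libraries had similar estimated depths of about 10300000 and 9090000 fragments. In the control library 12147 genes reached 1 FPKM and in the other library 12261 did.

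Dot1l itself was not lower in the library labelled Dot1l knockout. It was listed at 5.86 FPKM in the control library and 10.4 FPKM in the other, a 1.77-fold higher value and a log2 difference of 0.73. It remained above 0 under every pseudocount and scaling tried. The value covers the whole gene, and the deleted part is not given in the sources used here. Reads from outside that part would still be counted, so this value does not check the label, and the second library is called the library labelled knockout throughout. Among 13296 genes at 1 FPKM or more in either library, 2231 were at least 2-fold higher in the library labelled knockout, 2060 were at least 2-fold lower and 9005 lay within 2-fold. When each library was rescaled to a sum of 1000000, the split was 1900 higher and 3335 lower, and the median of all genes moved from 0.00 to -0.33 on the log2 scale. The greatest differences lay mostly on one side: 506 genes were at least 8-fold higher and 62 at least 8-fold lower.

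Genes of lymphatic identity were mostly lower in the library labelled knockout. Prox1, the transcription factor that specifies lymphatic fate, was 59.3 FPKM in control and 13.1 in the library labelled knockout, 4.54-fold lower. Flt4, the receptor for VEGF-C, was 71.9 and 14.1 FPKM, and Nr2f2, a transcription factor that acts with Prox1, was 23.7 and 4.29. The largest log2 difference of the list was in Sox18, an upstream activator of Prox1, with 18.4 against 1.28 FPKM, followed by Reln, a secreted glycoprotein of collecting vessels, with 87.5 against 11.4. Of 17 measured genes of this list, 12 were at least 2-fold lower, 3 at least 2-fold higher and 2 within 2-fold. The 3 higher genes were the scavenger receptors Stab1 (68.6 and 231 FPKM) and Stab2 (2.36 and 9.30), and the integrin Itga9 (20.5 and 61.7). Lyve1, the hyaluronan receptor used to mark LECs, was 526 FPKM in control and 552 in the library labelled knockout. Lyve1 and Stab1 are also expressed by some tissue macrophages. The list median was -2.04, below all 10000 matched random lists. The list mean was -1.27. In the same library fibroblast markers (median -2.14) and pericyte markers (median -2.57) were lower and macrophage markers (median 6.12) higher.

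The genes common to all endothelium differed in the same direction. Of 23 measured pan-endothelial genes, 19 were at least 2-fold lower in the library labelled knockout and none was at least 2-fold higher. Pecam1 was 218 and 49.2 FPKM, Cdh5, the cadherin of endothelial junctions, was 227 and 34.4, Tek was 79.5 and 11, and Cd34 was 177 and 18.5. The 4 genes within 2-fold were Ptprb (30.1 and 15.6 FPKM), Eng (29.8 and 16.7), Fli1 (61.3 and 61.2) and Tal1 (8.27 and 16.4), of which Fli1 and Tal1 are also transcription factors of blood cells. The median of the list was -1.86, a 3.63-fold lower level. Among 25 genes of blood endothelium 17 were at least 2-fold lower and 1 higher, with a median of -1.44. Aplnr, the apelin receptor, was 52.8 and 2.44 FPKM, Flt1 was 19.3 and 2.62, and the Notch target Hey1 was 18.9 and 2.52. Both lists lay below all 10000 matched random lists. Fibroblast markers were lower as well, with a median of -2.14, and macrophage markers were higher, with a median of 6.12.

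Genes of lymphatic valve formation and growth signalling were lower on balance. In the valve list 13 of 26 genes were at least 2-fold lower and 2 at least 2-fold higher in the library labelled knockout, with a median of -0.96. Cldn11, a claudin, was 20.4 and 0.641 FPKM, Foxc2, the forkhead factor of valve cells, was 6.16 and 0.342, and Gja4, which encodes connexin 37, was 45.1 and 3.82. Gata2, a valve regulator that mast cells also express, was 6.59 and 81.0, 12.3-fold higher. Several valve genes differed less, among them Nfatc1 (19.2 and 15.3 FPKM), Piezo1 (19.2 and 14.5) and Fn1 (116 and 147). In the growth list 15 of 25 genes were at least 2-fold lower and 1 higher, with a median of -1.32. Ramp2, the co-receptor for adrenomedullin, was 156 and 9.97 FPKM, while its partner Calcrl was 49.3 and 33.5. The VEGF receptor Kdr was 188 and 29.7, the chemokine scavenger Ackr3 6.40 and 0.645, and Angpt2 45.6 and 40.1. The single higher gene was Ramp3, at 0.673 and 9.87. Both medians lay below all 10000 matched random lists. Pan-endothelial genes (median -1.86) and fibroblast markers (median -2.14) were lower and macrophage markers (median 6.12) higher in the same library. Relative to the pan-endothelial median, a comparison chosen after seeing the data, the medians of the valve, growth and blood endothelial lists were 0.90, 0.54 and 0.42, at percentiles 96.1, 67.3 and 49.8 of random lists from the 5 endothelial lists, and that of the lymphatic identity list was -0.18, at percentile 1.27. Against the pan-endothelial list alone, the lymphatic identity list did not stand apart, by median (percentile 10.8) or by mean, which was higher by 0.43 (percentile 84.1).

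**Figure D1:**
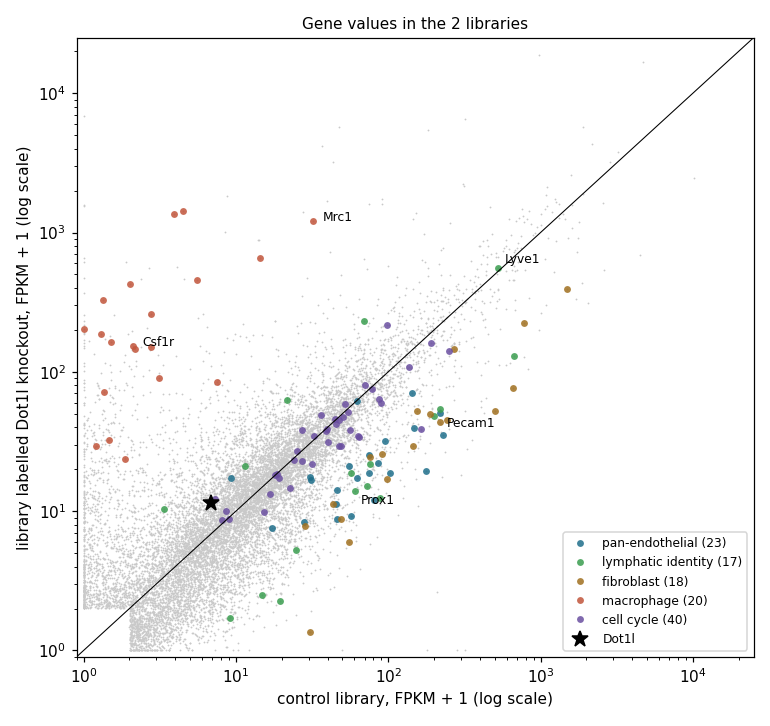
FPKM + 1 of each gene in the control library (horizontal, log scale) and the library labelled Dot1l knockout (vertical, log scale), for genes at 1 FPKM or more in either; coloured points are members of 5 gene lists and the star is Dot1l. Macrophage genes sit far above the line of equality, pan-endothelial, lymphatic identity and fibroblast genes mostly below it, and cell cycle genes along it.

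Of the 31 lists with a value, the macrophage list had the largest median difference. All 20 measured macrophage markers were at least 2-fold higher in the library labelled knockout, with a median difference of 6.12 on the log2 scale. Csf1r, the receptor that macrophages need for survival, was 1.1 FPKM in control and 152 in the library labelled knockout. Adgre1, which encodes F4/80, was 0.507 and 163, the complement gene C1qa was 1.01 and 429, and Mrc1, the mannose receptor, was 31.1 and 1211. Markers of other stromal and epithelial cells were lower. The control library itself held transcripts of such cells: all 18 measured fibroblast genes were at 10 FPKM or more in it. All 11 pericyte and smooth muscle genes (median -2.57) and 17 of 18 fibroblast genes were at least 2-fold lower, as were 8 of 14 keratinocyte genes (median -1.08). Col3a1 was 1481 and 391 FPKM, Dcn 503 and 51.1, Rgs5 39.2 and 2.46, and Krt14 35.4 and 16.3. The melanocyte and Schwann cell list (median -1.35) had 7 of 12 genes at least 2-fold lower, while Kit and Mitf, which mast cells also use, were higher. The median of this list was -0.51 with no minimum FPKM, where it did not stand apart (percentile 5.9). Skeletal muscle genes had a median of -0.87. Erythroid genes (median -0.36) did not stand apart. The platelet list had a median of 1.69 over 6 genes, led by Pf4, which embryonic macrophages also express. With no minimum FPKM its median was -0.039 and the list did not stand apart (percentile 40.8).

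Inflammatory genes were mostly higher in the library labelled knockout. Among 24 chemokines, cytokines and related genes 18 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 2.38. Cxcl2 was 0.894 FPKM in control and 616 in the library labelled knockout, Il1b 0.174 and 134, Ccl2 5.12 and 259, and Il6 1.0 and 110. The 2 lower genes, Cxcl12 (19.1 and 3.91) and Il7 (10.2 and 1.94), are made by stromal and endothelial cells. In the interferon and antigen presentation list 19 of 31 genes were at least 2-fold higher and none at least 2-fold lower, with a median of 1.43. The immunoproteasome gene Psmb8 was 3.84 and 54.4 FPKM. The class I genes H2-K1 (16.4 and 176) and H2-D1 (48.2 and 493) have near-identical relatives and their split is uncertain. Both medians lay above all 10000 matched random lists, in the library where macrophage markers were higher. Members of low value in control weigh on both medians. Among members at 10 FPKM or more in control, 7 chemokine and cytokine genes had a median of 0.49, from -2.04 to 2.47. For 7 interferon and antigen presentation genes at that level it was 0.80, from -0.13 to 3.35.

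HOX genes, matrix genes and developmental signalling genes were lower. All 29 measured HOX, MEIS and PBX genes had lower values in the library labelled knockout and 20 were at least 2-fold lower, with a median of -1.38. Hoxd8 was 71.1 and 13.9 FPKM, Hoxd10 18.7 and 1.56, Hoxb7 16.1 and 3.48, and Meis1, a HOX partner, 19 and 7.73. In the basement membrane and matrix list 20 of 29 genes were at least 2-fold lower, with a median of -1.74. Lama4, a vascular laminin chain, was 216 and 42.2, and Sparc 1002 and 263, whereas Thbs1 was 72.7 and 170. Junction and integrin genes had a median of -1.13 with 15 of 26 at least 2-fold lower, and Notch and Wnt genes had a median of -1.29 with 22 of 34 at least 2-fold lower. Both share members with the endothelial lists above, among them Cdh5, Cldn5 and Gja4 for junctions and Notch1, Dll4 and Hey1 for Notch. The Notch target Hes1 was 116 and 32.4 FPKM and Wnt5a 12.4 and 2.69, while Rbpj, the DNA-binding factor of the Notch pathway, was 8.70 and 50.5. These 4 lists lay below all 10000 matched random lists. The TGF-beta and mesenchymal list was divided, with 12 of 30 genes at least 2-fold lower and 6 at least 2-fold higher, and its median of -0.68 also lay below all 10000 matched random lists. Acta2 was 56.0 and 6.27 and Cdh2 11.2 and 0.706, against Tgfbi with 26.5 and 154 and Id2 with 28.3 and 153. In the same library pan-endothelial and fibroblast markers had medians of -1.86 and -2.14, and macrophage markers of 6.12.

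Genes of cell division, transcription elongation, chromatin and ribosomes mostly lay within 2-fold, as did 9005 of all 13296 genes. In the cell cycle list 38 of 40 genes lay within 2-fold, with a median of -0.089. Of the 40 genes 28 had lower values and 12 higher ones, and the list mean lay at percentile 3.2. Top2a was 189 FPKM in control and 161 in the library labelled knockout, and Mki67 250 and 141. The exceptions were Ube2c (164 and 37.7) and Pcna (97.7 and 215). Among 23 partners of DOT1L and of the elongation machinery 17 lay within 2-fold (median -0.13), 3 were higher and 3 lower. Mllt10, a direct partner, was 18.3 and 17.4, Men1 was 20.6 and 8.77, and Aff1 was 4.80 and 22.6. Chromatin and DNA methylation enzymes had 31 of 35 genes within 2-fold (median 0.17), with Ezh2 at 38.5 and 28.9 and Kmt2d at 3.23 and 13.9. Of 52 ribosomal protein genes 46 lay within 2-fold (median 0.25). None of these 4 medians stood apart from the random lists, and none did when each library was rescaled to a sum of 1000000, where the medians of the cell cycle, partner, chromatin and ribosomal lists were -0.44, -0.48, -0.17 and -0.10, beside a shift of all genes of -0.33. The p53 and cyclin-dependent kinase inhibitor list did not stand apart (median 0.19, or -0.10 after that rescaling), and its members went both ways: Cdkn1a, which encodes p21, was 3.46 and 39.9 FPKM, Pmaip1 2.24 and 54.6, and Cdkn1c 407 and 60.6. Macrophage markers were higher in the same library (median 6.12). Which cells the values of these lists came from was not tested.

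Metabolic and stress genes were higher in part. Of 29 glycolysis and hypoxia genes 18 were at least 2-fold higher and none at least 2-fold lower, with a median of 1.27, above all 10000 matched random lists. Ldha, which makes lactate, was 171 and 977 FPKM, the hexokinase Hk2 4.94 and 38.8, and the lactate exporter Slc16a3 3.01 and 35.8, while Hif1a was 91.5 and 47.0. Unfolded protein and heat shock genes had a median of 0.78 (percentile 99.9), led by the haem-degrading enzyme Hmox1 at 13.2 and 886 and by Hspa1a at 1.08 and 47.8. Sterol and lipid genes did not stand apart (median -0.27), although Fabp4 was 1699 and 330 and Scd1 9.89 and 1.03. Immediate early genes, which rise when tissue is dissociated, had a median of 0.96 with 7 of 17 at least 2-fold higher. Among them Atf3 was 36.5 and 265, and Ier3 28.1 and 468, with Fos at 518 and 537. Common reference genes were also higher, with a median of 0.70 (percentile 99.5), or 0.35 with each library rescaled to a sum of 1000000. By its mean the list did not stand apart (percentile 97.0). Macrophage markers were higher in the same library (median 6.12). Actb was 1572 and 2574, and Gapdh 98.0 and 172, and both kept this direction under every scaling.

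The sex-linked genes differed between the pools. Xist, the RNA of the inactive X chromosome, was 48.6 FPKM in control and was listed at 0 in the library labelled knockout. Its antisense partner Tsix, which overlaps it, was 0.843 and 0.0791. All 4 Y-linked genes were higher in the library labelled knockout: Ddx3y was 28.5 and 77.4, Eif2s3y 16.6 and 69.2, Uty 6.55 and 20.9, and Kdm5d 6.96 and 13.1.

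Many of the largest differences among genes at 10 FPKM or more were in genes of macrophages and mast cells. The 15 highest were Pf4 (2.92 and 1361 FPKM), Cxcl2, F13a1 (3.51 and 1434), C1qb, C1qa, Hdc (7.74 and 1818), Fcgr3, C1qc, Rgs1, Ccl12, Calca, Fcna, Cd163, Mcpt4 (3.13 and 565) and Clec4n. C1qc and Ccl12 were listed at 0 in the control library. Hdc encodes the enzyme that makes histamine and Mcpt4 a mast cell protease. The 15 lowest were Rprl3, Rprl2, Car3, Xist, Mfap5, Sprr1a, Nnat, Hist1h2ah, Adipoq, Aplnr, Efemp1, Nov, Ramp2, Gpd1 and Sema3c. Car3 was 207 and 1.61 FPKM, and Adipoq, which encodes the adipocyte hormone adiponectin, was 30.2 and 0.926. Rprl3 and Rprl2, listed at 0 in the library labelled knockout, resemble the RNase P RNA gene Rpph1, which was 973 and 18808, and Hist1h2ah has near-identical copies, so the reads of these genes are not securely assigned.

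**Figure D2:**
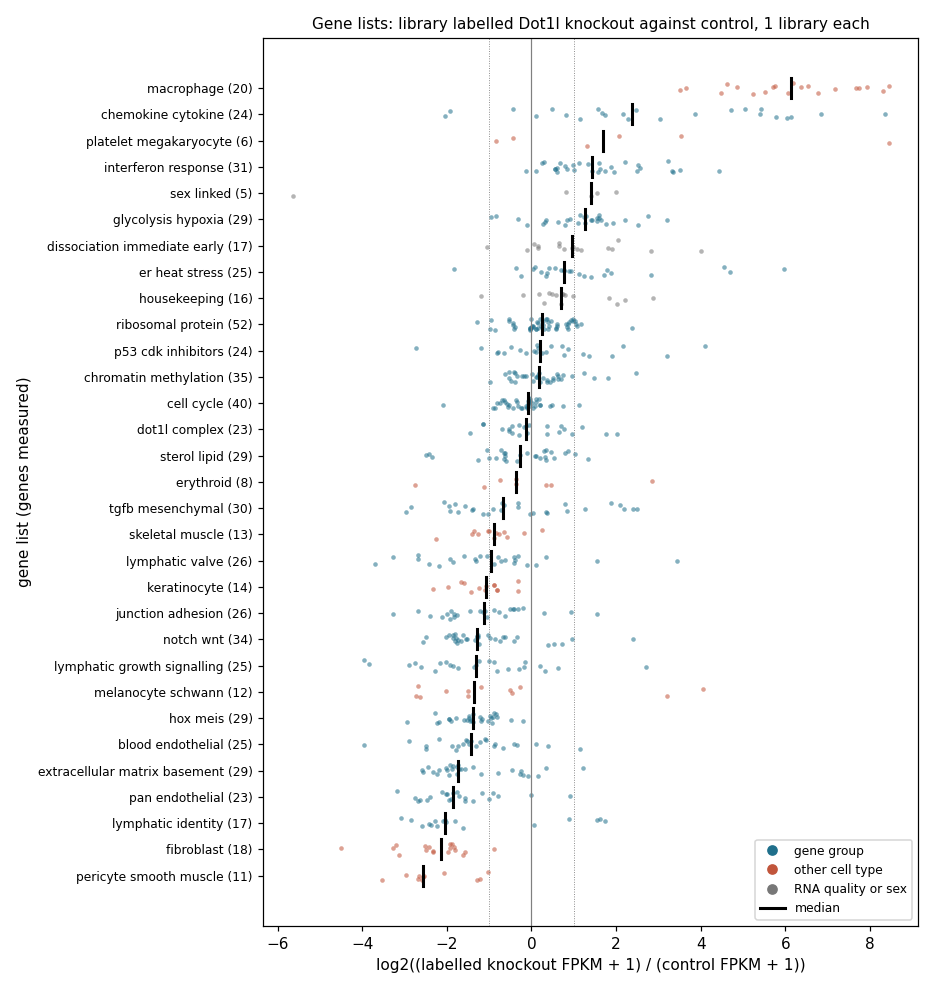
Log2 difference, log2((labelled knockout FPKM + 1) / (control FPKM + 1)), of each measured member (points) and the median (black bar) of 31 gene lists, with the number of genes measured in brackets; dotted lines mark 2-fold. Macrophage genes have a median of 6.12 and pan-endothelial, fibroblast and pericyte genes medians of -1.86 or lower, with cell cycle genes near 0.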

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

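No paired analysis was possible because each genotype has 1 library, and no replicate could be left out, so nothing here measures the spread between embryos or pools. Dot1l stayed higher in the library labelled knockout, with log2 differences of 0.50 (pseudocount 5), 0.44 (each library rescaled to a sum of 1000000) and 0.61 (same upper quartile) against 0.73. The 2231 genes at least 2-fold higher became 1323 with a pseudocount of 5, 3464 at 1.5-fold and 1298 at 3-fold. The 2060 at least 2-fold lower became 921, 3450 and 906, and 3335 with each library rescaled to a sum of 1000000. The summed FPKM were 530294 in the library labelled knockout and 415537 in control, so that rescaling lowers most log2 differences, but it raises those of some genes of low value in control. Small RNAs took 8.27% of the sum in the library labelled knockout and 0.964% in control. These shares leave out the RNA genes Rpph1 (973 FPKM in control and 18808 in the other library) and Rmrp (4688 and 16682). Leaving out markers of other cell types gave 2205 higher and 2010 lower, and leaving out also the blood cell and adipocyte lists added after seeing the data gave 2175 and 2000. Only the listed genes are dropped in this way. The step cannot remove RNA of other cell types from the remaining genes, so the small change in the counts says nothing about its share. The 7 main lists kept their direction and their place inside or outside the random lists under all alternatives chosen before the data were examined, except for the direction of the DOT1L partners, whose mean was 0.06 against a median of -0.13. The comparison with the pan-endothelial median was chosen after seeing the data. It gives a value above 0 to any list whose median is less negative than -1.86, so it does not make the genes higher. Lower values were found for 22 of 26 valve, 21 of 25 growth signalling and 22 of 25 blood endothelial genes. Relative to the median of the pan-endothelial list, the valve median was 0.90, the growth signalling median 0.54 and the blood endothelial median 0.42, none outside random lists drawn from the 5 endothelial lists, while lymphatic identity was -0.18, at percentile 1.27, but at 10.8 by median and 84.1 by mean (a difference of 0.43) against the pan-endothelial list alone. Of the other lists, platelet genes reversed to -0.039 with no minimum, because genes near 0 then enter. Muscle genes, melanocyte and Schwann cell genes, reference genes (by mean) and sex-linked genes (by mean) no longer stood apart under 1 or 2 settings each, and the cause was not tested. Depth limits genes of low value: at the estimated depths, 1 FPKM in a 2 kb transcript rests on about 20.5 fragments in control and 18.2 in the other library. These estimates hold only if the deposited values were not scaled further.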

Other observations

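The tests in this part, the 5 added gene lists and the explanations weighed were chosen after the results were seen. Mast cell and basophil genes were among the most abundant transcripts of the library labelled knockout. All 21 genes of a list of such genes were at least 2-fold higher, with a median log2 difference of 5.78. The mast cell protease Cma1 was 46.2 FPKM in control and 5706 in the library labelled knockout, Cpa3 35.8 and 4211, Tpsb2 3.55 and 459, and the receptor subunit Ms4a2 0.174 and 34.4. Mcpt8 and Il4, both made by basophils, were listed at 0 in control and at 57.2 and 85.7 in the other library. Neutrophil genes had a median of 4.69 with 7 of 8 at least 2-fold higher, among them S100a9 at 1.63 and 205. Of 16 lymphocyte genes only 6 reached 1 FPKM in either library, with a median of 1.74, and Cd4, which macrophages also carry, was the most abundant of them at 0.133 and 9.77 FPKM.

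Imprinted genes of embryonic growth were lower in the library labelled knockout, with 18 of 22 at least 2-fold lower and a median of -1.89. H19, the most abundant gene of the control library, was 10202 and 2447 FPKM, Igf2 977 and 199, Grb10 250 and 38.2, and Mest 632 and 114. Adipocyte genes had a median of -2.43, with 9 of 10 at least 2-fold lower. In the same library fibroblast (median -2.14), pericyte (-2.57) and matrix genes (-1.74) were lower and macrophage markers (6.12) higher. Of 60 measured histone cluster genes, whose copies share reads, 39 were at least 2-fold lower and none at least 2-fold higher. Small nucleolar and Cajal body RNAs went the other way, with 32 of 33 at least 2-fold higher, and FPKM of such short genes depends strongly on fragment length.

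Endothelial, lymphatic and HOX genes were lower together in the library labelled knockout. The scale of the deposited FPKM is argued against as the whole cause, because cell cycle genes had a median of -0.089, and of -0.44 against -2.24 for pan-endothelial genes with each library rescaled to a sum of 1000000. How the cells were purified is not given in the sources used here. A larger share of myeloid and mast cell RNA in the library labelled knockout would go with all 20 macrophage markers being higher. It would also go with fibroblast markers being lower by about as much as pan-endothelial ones (difference of medians -0.26 among genes at 10 FPKM or more in control). That share alone would lower all other cell types alike. Among such genes the medians were -1.07 for 7 keratinocyte, -1.88 for 22 pan-endothelial and -2.58 for 8 pericyte genes. Other differences in cell makeup or expression therefore stay open. The adipocyte median was -3.14 over 6 genes, but that list was chosen after seeing the data and is not weighed here. A further loss of lymphatic identity genes within the endothelial cells stays open: the list median lay at percentile 1.27 of random lists from the 5 endothelial lists, but against the pan-endothelial list alone its median was at percentile 10.8 and its mean at 84.1, and an effect of the genotype on the myeloid cells of skin was not tested.

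Dot1l was not lower in the library labelled knockout. Transcripts of cells other than endothelium and an exchange of the 2 libraries cannot be told apart with the values at hand. Its log2 difference lay 2.59 above the pan-endothelial median, but this restates the observation and would be the same under either explanation. The FPKM ratio of 1.77 was below the 2-fold set for an exchange, but that level was set after the ratio was seen and so cannot decide. The deleted part of the gene is not given in the sources used here. Reads from outside that part were not tested.

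Xist was listed at 0 in the library labelled knockout while all 4 Y-linked genes were higher, with a median log2 difference of 1.47 and folds from 1.88 to 4.17. A different sex mix of the pooled embryos stays open, because these values are the observation itself and no independent test was made, and because a value of exactly 0 can be a failed estimate. With 1 pool per genotype, a difference in sex mix could not be separated from the genotype in any other gene. No biological explanation was tested.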
